A study of Homo sapiens and Mus musculus with 55 samples.

How the data were processed

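RNA was extracted with a Maxwell RSC simplyRNA kit per the labels and sequenced on Illumina instruments, and 55 libraries were deposited in 10 tables. The labels give no times, doses or growth protocols. The unit of the deposited values is signal, here gene read counts that the authors divided by 1 factor per library within each table. The submitters' processing notes name HISAT2, featureCounts, StringTie and DESeq2 without versions, and the genome build is not given in the sources used here, so no coordinates are reported. Within a tolerance of 0.05, 100% of values were whole multiples of 1 step per library, so whole reads were recovered. Recovered depth was 5663610 to 13191675 reads per library. A count of 0 leaves room for up to 3 reads over a group, which was used as the floor for every fold against a group at 0. Reads were turned into normalized values with the mean value of 1 read in that group, so these folds are ratios of normalized means. With 1 to 3 reads the ratio has an exact 95% interval from the reads of both groups, which covers counting error only.

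Libraries were grouped by cell line and labelled treatment, 0 columns were left unmapped, and each table, normalized separately, was fitted alone. Genes with a table mean of at least 10 were tested by limma-trend on log2(value + 1), two-sided, with Benjamini-Hochberg adjusted p below 0.05. In tables with 2 perturbed groups the contrast was their mean minus the control. Nothing says replicates were separate cultures, so p-values measure spread within groups, not between siRNAs or sgRNA groups. R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0 were used. In simulated data with 200 genes changed 2-fold, the test found 90.5 to 97.5%, with 3 to 14 false calls. Real tables had 3134 to 10976 calls, so this is no error rate for them.

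The groups, tests, 28 gene lists, rule for named genes and most alternatives were fixed before the data were examined. Lists with at least 4 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Of all list calls, 1 held with an estimated correlation, that of interferon-stimulated genes in MDA-MB-436 with STING sgRNA. The lists cover the cGAS-STING pathway, RNA sensors, interferon-stimulated genes, T cell-attracting chemokines, inflammatory NF-kB targets, class I and class II presentation, immune checkpoint ligands, MYC-activated genes, nucleotide synthesis, E2F and replication, mitosis, oxidative phosphorylation, glycolysis and hypoxia, cholesterol synthesis, the unfolded protein and amino acid response, p53 targets, tubulins and microtubule regulators, drug efflux transporters, DNA methylation and chromatin repressors, mitochondrially encoded transcripts, and markers of epithelial, mesenchymal, basal, fibroblast, endothelial, myeloid and T cells. The fibroblast and mesenchymal lists share 3 collagens. Named genes are MYC, STING1, CGAS, CCL5, CXCL10 and CXCL11 throughout, up to 4 members of each list with the largest called change, and the 3 highest and 3 lowest called genes with a mean of at least 50 and groups that do not overlap. STING1 was listed as TMEM173 (mouse Tmem173), CGAS as MB21D1 in human, and RIGI as DDX58 (mouse Ddx58).

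Fisher's exact test compared directions, not overlap size, for genes tested and called in both comparisons. Agreement between 2 siRNAs or 2 sgRNA groups was set against independent lists and 20 simulations of unchanged groups. Alternatives were a pseudocount of 4, no filter, quantile normalization, the replicate number as a block, edgeR and DESeq2 on recovered reads, each reagent alone, a change of at least 2-fold, each library left out, fry, an estimated correlation, and the 500 genes of lowest p in overlaps. A correction for transcript GC content (loess span 0.3, human tables, 82.5 to 85.4% of genes with a value) and the 2 MDA-MB-436 Tax-R libraries counted as 1 were added after the data were seen. XIST and Y-linked genes were left out of every table. A few genes selected by the rule for named genes are withheld.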

Results

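RNA sequencing of 55 libraries from 4 breast cancer cell lines was deposited as 10 tables of normalized counts, each normalized on its own. MDA-MB-436 and SUM159PT are human triple-negative lines, and 4T1 and Py230 are mouse mammary tumour lines. The series title concerns repression of STING by MYC, the immune response to tumours and immune checkpoint inhibitors. STING (gene STING1) is the adaptor that passes on the detection of cytosolic DNA by the enzyme cGAS (gene CGAS), and MYC is a transcription factor that drives growth. Parental cells and cells labelled Tax-R were compared in both human lines with 2 libraries per group. Tax-R cells of both lines and 4T1 cells received a control siRNA or either of 2 MYC siRNAs, with 2 libraries per human group and 3 per 4T1 group. Mock cells and 2 groups with a STING sgRNA, labelled C1 and C2, had 2 libraries each in both human lines, as did cells with a STING sgRNA plus a GFP or a STING open reading frame (ORF). Py230 cells with a Sting1 shRNA were given vehicle or doxycycline, with 3 libraries each. STING1, human CGAS and RIGI were listed as TMEM173, MB21D1 and DDX58. Values are normalized counts as mean ± SD over the libraries of a group, and changes are log2 fold changes on the log2(value + 1) scale ± SE. Genes said to be higher or lower, to rise or to fall passed limma's test at adjusted p below 0.05. Exceptions show a higher adjusted p or are marked untested.

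In MDA-MB-436, Tax-R cells had less STING1 transcript than parental cells and almost none of several chemokines that recruit T cells, while the efflux pump ABCB1 was far higher. STING1 was at 396.6 ± 21.32 in parental and 193.6 ± 3.391 in Tax-R libraries (n = 2 each, -1.03 ± 0.07, limma adjusted p = 2.65e-07), and CGAS was lower too (-0.37 ± 0.05). MYC did not pass the threshold (1324 ± 57.7 against 1261 ± 25.68, n = 2 each, limma adjusted p = 0.174, but -0.11 and 0.0402 after quantile normalization). ABCB1, which exports taxanes and other drugs, rose from 55.1 ± 1.627 to 2761 ± 39.06 (5.62 ± 0.05), and the related transporter ABCB4 rose by 3.59 ± 0.24. Of 19085 genes tested, 5282 were higher and 5139 lower in Tax-R cells, and 541 and 1752 of these changed at least 2-fold.

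The T cell-attracting chemokines fell as a list in MDA-MB-436 Tax-R cells, with 5 of 6 measured members lower and 1 higher, and the same counts adjusted over the list alone. The list median was -4.73, or -4.41 with CX3CL1 at its bound (camera adjusted p = 0.0052, and 0.69 with an estimated correlation). CXCL10 had 2 reads in all in the Tax-R libraries, a 91.4-fold lower mean with a 95% counting interval of 25 to 760, and CXCL11 had 3 reads, 103-fold lower with an interval of 34.9 to 502. CCL5 fell by 3.96 ± 0.41, and CX3CL1 had no read in the Tax-R libraries, at least 29.2-fold lower against a floor of 3 reads over the group. Inflammatory NF-kB targets fell, with 17 of 20 lower and 1 higher, or 19 and 1 adjusted over the list alone (camera adjusted p = 6.5e-07, and 0.65 with an estimated correlation). Examples were the cytokine IL6 (-2.58 ± 0.15), the apoptosis inhibitor BIRC3 (-2.38 ± 0.06) and the adaptor TRAF1 (-1.94 ± 0.19). Interferon-stimulated genes fell, with 24 of 42 lower and 5 higher also adjusted over the list alone (median -0.23, camera adjusted p = 0.002, and 0.69 with an estimated correlation). EPSTI1 (-3.32 ± 0.23), the antiviral proteins IFIT2 (-1.94 ± 0.08) and OASL (-1.92 ± 0.08), and TRIM22 (-1.73 ± 0.16) fell most among them.

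Replication genes of the E2F list rose slightly in MDA-MB-436 Tax-R cells, with 21 of 26 higher and none lower (21 and 0 adjusted over the list alone, camera adjusted p = 2.5e-05, and 0.69 with an estimated correlation). POLE2 (0.68 ± 0.05) and the helicase subunit MCM5 (0.62 ± 0.03) were examples. Nucleotide synthesis genes rose, with 17 of 21 higher, 18 adjusted over the list alone, and none lower (camera adjusted p = 0.00016, and 0.69 with an estimated correlation). An example was TYMS, of thymidylate synthesis (0.54 ± 0.05). MYC-activated genes, mostly ribosome biogenesis factors, were higher for 20 of 36 and lower for none, adjusted over all genes or adjusted over the list alone, led by NPM1 (0.56 ± 0.04), with a median of 0.15. That call (camera adjusted p = 0.004) was lost after quantile normalization (adjusted p = 0.094, and 0.69 with an estimated correlation). Basal keratins and basal markers fell, with 5 of 6 lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.014, and 0.69 with an estimated correlation). KRT17 fell to 3 reads, 192-fold lower with an interval of 65.4 to 934, the integrin ITGB4 by 3 ± 0.16, and TP63, the transcription factor of basal cells, by 1.2 ± 0.07. Fibroblast markers were lower for 4 of 5, as they were adjusted over the list alone, led by the collagen COL3A1 (-4.54 ± 0.14) and the protease FAP (-3.34 ± 0.15). Their camera adjusted p of 0.037 became 0.061 after GC correction and 0.056 with the replicate number as a block (adjusted p = 0.69 with an estimated correlation). The other 17 of 25 lists did not pass, at adjusted p from 0.1 to 1.

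The lowest fold changes in MDA-MB-436 Tax-R cells were those of the collagen COL11A1, the protease BACE2 and the ephrin receptor EPHA3, each without a read in the Tax-R libraries. Against the floor of 3 reads they were at least 1.59e+03-fold, 481-fold and 446-fold lower. The highest were MAGEA11, a cancer-testis antigen (6.76 ± 0.18), APCDD1L (6.13 ± 0.19) and CORO2B, 145-fold higher with an interval of 39.6 to 1.2e+03. Other human replicate pairs had a chi-square per gene, 1 for sampling noise, of 1.02 to 2.94. The 2 Tax-R libraries were below 1 (0.85 over 18264 genes), though not over the 91 most abundant (9). Counting them as 1 sample left 8979 genes called.

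SUM159PT Tax-R cells also had less STING1, lost the same 3 focus chemokines and gained ABCB1, and they lost epithelial and gained several mesenchymal transcripts. STING1 was at 528 ± 41.04 in parental and 160.4 ± 5.556 in Tax-R libraries (n = 2 each, -1.71 ± 0.08, limma adjusted p = 2.03e-07). MYC (1402 ± 131.2 against 1511 ± 8.457, n = 2 each, limma adjusted p = 0.149) and CGAS (-0.12 ± 0.05, limma adjusted p = 0.0992, but -0.18 and 0.0278 after quantile normalization) did not pass the threshold. ABCB1 rose from 357.8 ± 2.866 to 2705 ± 2.498 (2.91 ± 0.04), and the efflux pump ABCG2 rose by 1.09 ± 0.07. Of 18370 genes tested, 4322 were higher and 4064 lower, of which 589 and 1424 changed at least 2-fold.

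The T cell-attracting chemokines fell in SUM159PT Tax-R cells, with 3 of 5 lower, none higher and the same counts adjusted over the list alone (median -4.19, camera adjusted p = 0.0035, and 0.38 with an estimated correlation). CXCL10 had no read, at least 30.3-fold lower, CCL5 had 1 read, 84.1-fold lower with an interval of 14.7 to 3.36e+03, and CXCL11 had 2 reads, 35.5-fold lower with an interval of 9.46 to 299. Interferon-stimulated genes fell, with 33 of 42 lower and 1 higher, also adjusted over the list alone (median -0.53, camera adjusted p = 3.1e-09, and 0.38 with an estimated correlation). HERC5, the ligase for ISG15 (-2.66 ± 0.15), and MX2 (-3.31 ± 0.31) were examples. Inflammatory NF-kB targets fell, with 12 of 20 lower and 4 higher, also adjusted over the list alone (camera adjusted p = 0.031, and 0.64 with an estimated correlation). IL6 fell by 3.4 ± 0.24, while the cytokines LIF (1.42 ± 0.1) and CSF2 (1.35 ± 0.27, DESeq2 adjusted p = 0.146) rose.

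Epithelial markers fell in SUM159PT Tax-R cells, with 6 of 9 lower and none higher by both adjustments, the second being adjusted over the list alone (camera adjusted p = 0.002, and 0.38 with an estimated correlation). Examples were ELF3 (-3.85 ± 0.3), CLDN7 (-2.74 ± 0.21) and KRT8 (-0.65 ± 0.04). Basal keratins and basal markers fell, with 6 of 8 lower and 2 higher, also adjusted over the list alone (camera adjusted p = 0.011, and 0.38 with an estimated correlation). Examples were KRT5 (-4.2 ± 0.22), KRT6A (-3.62 ± 0.2) and ITGB4 (-3.33 ± 0.18). Mesenchymal markers rose, with 13 of 19 higher and 2 lower, also adjusted over the list alone (median 0.31, mean 0.01, camera adjusted p = 0.0039, and 0.38 with an estimated correlation). COL6A3 (1.42 ± 0.04), SNAI2, a repressor of epithelial genes (1.29 ± 0.07), and COL5A1 (1.03 ± 0.04) rose, and COL3A1 fell by 7.15 ± 0.47. Fibroblast markers, which share 3 collagens with that list, fell, with 4 of 6 lower and 1 higher, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.035, and 0.38 with an estimated correlation). Examples were PDGFRA (-2.04 ± 0.14) and DCN (-1.98 ± 0.12).

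Tubulins, which form the microtubules that taxanes bind, and microtubule regulators rose as a list in SUM159PT Tax-R cells, with 13 of 18 higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.0067, and 0.38 with an estimated correlation). The microtubule-associated proteins MAPT (3.09 ± 0.24) and MAP1B (0.75 ± 0.04) rose, and MAP2 fell by 1.28 ± 0.04. E2F and replication genes rose, with 22 of 26 higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.00054, and 0.38 with an estimated correlation). An example was E2F1 (0.52 ± 0.04). MYC-activated genes were higher for 16 of 36 and lower for 1, or 16 and 2 adjusted over the list alone, with a median of 0.1, and BOP1 (0.52 ± 0.05) was among those higher. Their call (camera adjusted p = 0.0039) was lost after quantile normalization (adjusted p = 0.072, and 0.47 with an estimated correlation). Cholesterol synthesis genes fell, with 12 of 18 lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.0039, and 0.38 with an estimated correlation). Among them INSIG1 fell by 0.85 ± 0.04 and CYP51A1 rose by 1.98 ± 0.15. Glycolysis and hypoxia genes fell, with 13 of 25 lower and 4 higher, also adjusted over the list alone (camera adjusted p = 0.031, 0.055 with the replicate number as a block, and 0.6 with an estimated correlation). Examples were CA9, a carbonic anhydrase induced by hypoxia (-1.4 ± 0.1), and ALDOC (-1.72 ± 0.11). Mitosis genes were lower for 9 of 24 and higher for none, also adjusted over the list alone, led by CDC25C (-0.34 ± 0.06, DESeq2 adjusted p = 0.0945), at a camera adjusted p of 0.031 that became 0.076 after GC correction and 0.064 with the block (adjusted p = 0.64 with an estimated correlation). The other 12 of 25 lists did not pass, at adjusted p from 0.14 to 0.65.

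In SUM159PT Tax-R cells the lowest named genes were COL11A1 (-9.69 ± 0.11) and the cancer-testis genes SSX2 and SSX2B, at least 532-fold and 500-fold lower, whose near-identical copies can share reads. The highest were the growth factors BMP7 (6.11 ± 0.23) and HGF (5.4 ± 0.1), and the potassium channel KCNMA1 (5.08 ± 0.11). Of 5573 genes called in both lines, 82.3% changed in the same direction (Fisher's exact test, log2 odds ratio 4.44). In both, 2321 were higher against 1246 for independent lists, and 2263 lower against 973. Genes are not independent replicates. DESeq2 on the recovered reads called 4209 genes in SUM159PT.

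**Figure D1:**
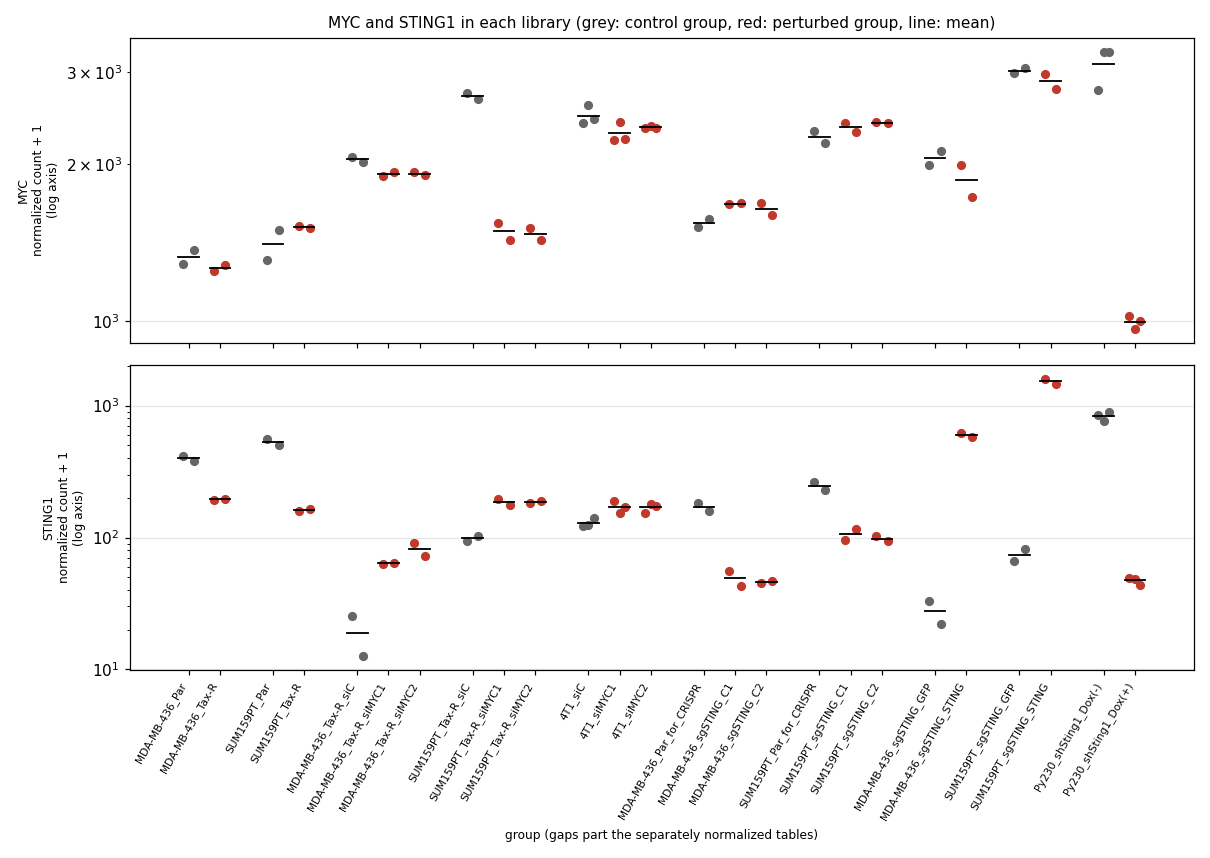
Normalized counts plus 1 (log axis) of MYC (top) and STING1 (bottom) in every library, with control groups in grey, perturbed groups in red and a line at each group mean. STING1 was lower in Tax-R, sgRNA and doxycycline groups and higher in MYC siRNA and STING ORF groups, while MYC fell clearly after SUM159PT MYC siRNA and Py230 doxycycline, and levels are not comparable between tables that were normalized separately.

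MYC siRNA in MDA-MB-436 Tax-R cells lowered the MYC transcript little. STING1, class I presentation genes and mesenchymal and fibroblast markers nevertheless rose, and MYC-activated, replication and mitosis genes fell. MYC was at 2058 and 2019 in the control siRNA libraries, 1897 and 1930 with siMYC1 and 1924 and 1907 with siMYC2 (-0.09 ± 0.03, limma adjusted p = 0.0144, DESeq2 adjusted p = 0.131). STING1 rose from 18.07 ± 9.086 (n = 2) to 62.55 ± 1.453 and 81.02 ± 12.84 (n = 2 each, 2 ± 0.21, limma adjusted p = 2.54e-09), and CGAS fell by 0.37 ± 0.08. CCL5, CXCL10 and CXCL11 stayed at group means of at most 4.122, below the filter. Of 15399 genes tested, 5235 were higher and 5193 lower, of which 1499 and 633 changed at least 2-fold.

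MYC-activated genes fell in these cells, with 33 of 35 lower and 1 higher, also adjusted over the list alone (median -0.8, camera adjusted p = 1.1e-10, and 0.09 with an estimated correlation). The RNA helicase DDX21 (-1.32 ± 0.04) and the nucleolar protein NOLC1 (-1.11 ± 0.04) were examples. Nucleotide synthesis genes were lower for 19 of 21 and higher for none, also adjusted over the list alone (camera adjusted p = 3.5e-06, and 0.15 with an estimated correlation). Examples were DHODH (-1.26 ± 0.12) and PFAS (-1.04 ± 0.05). E2F and replication genes were lower for 22 of 26 and higher for 2, also adjusted over the list alone (camera adjusted p = 1.7e-05, and 0.15 with an estimated correlation). An example was GINS1 (-1.17 ± 0.07). Mitosis genes were lower for 22 of 24 and higher for 1, also adjusted over the list alone (camera adjusted p = 2.7e-06, and 0.12 with an estimated correlation). Examples were the kinase AURKB (-1.16 ± 0.06) and CDC20 (-1.04 ± 0.04).

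Class I presentation genes rose in MDA-MB-436 with MYC siRNA, with 13 of 20 higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.021, and 0.16 with an estimated correlation). Examples were HLA-B (1.48 ± 0.04), HLA-C (1.13 ± 0.1) and the peptide transporter TAP1 (1.03 ± 0.08). Interferon-stimulated genes rose, with 25 of 40 higher and 8 lower, also adjusted over the list alone (camera adjusted p = 0.017, and 0.15 with an estimated correlation). Examples were MX2 (2.38 ± 0.32) and TRIM22 (2.01 ± 0.23), while OAS1 fell by 1.95 ± 0.37. Immune checkpoint ligands rose, with 8 of 10 higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.023, and 0.16 with an estimated correlation). Examples were LGALS9 (3.4 ± 0.28), CD276 (1.34 ± 0.03) and NT5E, which makes adenosine (1.06 ± 0.04). Mesenchymal markers were higher for 15 of 17 and lower for 1, or 16 and 1 adjusted over the list alone, with a median of 1.3 (camera adjusted p = 4.5e-06, and 0.16 with an estimated correlation), and all 4 measured fibroblast markers were higher, also adjusted over the list alone (camera adjusted p = 0.0037, and 0.15 with an estimated correlation). COL1A1 rose from 475.1 ± 6.007 to 7221 ± 17.88 and 6415 ± 121.2 (3.84 ± 0.03), COL5A1 by 3.22 ± 0.03 and PDGFRB by 3.14 ± 0.17. Glycolysis and hypoxia genes rose, with 19 of 25 higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.0011, and 0.15 with an estimated correlation). Examples were ALDOC (2.68 ± 0.14) and VEGFA, which drives vessel growth (1.81 ± 0.04). Genes of the unfolded protein and amino acid response rose, with 13 of 19 higher and 2 lower, or 14 and 2 adjusted over the list alone (camera adjusted p = 0.021, and 0.16 with an estimated correlation). An example was CHAC1 (2.21 ± 0.22). The other 11 of 22 lists did not pass, at adjusted p from 0.062 to 0.86.

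The lowest named genes with MYC siRNA in MDA-MB-436 were the tight junction gene CLDN1 (-3.11 ± 0.23), TRUB1 (-2.54 ± 0.12) and LSM6 (-2.53 ± 0.16). The highest were COL5A3 (108-fold for siMYC1 with an interval of 29.7 to 901 and 86.1-fold for siMYC2 with an interval of 23.5 to 717), the activin subunit INHBA (5.57 ± 0.18) and the cytokine IL33 (5.54 ± 0.14). ABCB1 fell by 0.78 ± 0.03. Both siRNAs called 8878 genes in the same direction and 0 in opposite directions, against 1588 higher plus 1556 lower for independent lists. Both were set against the same 2 control libraries, which could not be split, so part of the excess may come from those controls, and the siRNAs differed from each other for 30 genes.

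In SUM159PT Tax-R cells, MYC siRNA lowered MYC itself, and mitosis and replication genes fell by more than 2-fold in the median while STING1 and mesenchymal and fibroblast markers rose. MYC was at 2727 and 2663 in the control libraries, 1538 and 1428 with siMYC1 and 1504 and 1427 with siMYC2 (-0.87 ± 0.04, limma adjusted p = 3.97e-23). STING1 rose from 97.33 ± 5.754 (n = 2) to 185.5 ± 12.48 and 184.8 ± 6.195 (n = 2 each, 0.92 ± 0.1, limma adjusted p = 7.92e-11). CCL5 (0.9 ± 0.29, limma adjusted p = 0.00474, DESeq2 adjusted p = 0.127) and CXCL11 (1.8 ± 0.35) rose from group means of 11.42 ± 1.522 and 4.546 ± 2.35, and CXCL10 stayed below the filter with a highest group mean of 3.322 ± 1.743. CGAS fell by 0.41 ± 0.13 (limma adjusted p = 0.00348), a call lost with DESeq2 (0.0791) and without control replicate 1 (-0.2, 0.248). Of 15796 genes tested, 5525 were higher and 5451 lower, of which 1630 and 1342 changed at least 2-fold.

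All 24 mitosis genes fell, also adjusted over the list alone (median -2.23, camera adjusted p = 2e-12, and 0.055 with an estimated correlation), among them the kinase TTK (-2.51 ± 0.11) and TOP2A (-2.5 ± 0.05). E2F and replication genes were lower for 25 of 26 and higher for 1, also adjusted over the list alone (median -1.89, camera adjusted p = 1.8e-10, and 0.055 with an estimated correlation). Examples were the licensing factor CDT1 (-2.74 ± 0.09) and CDC45 (-2.68 ± 0.13). Nucleotide synthesis genes were lower for 20 of 21 and higher for 1, also adjusted over the list alone (camera adjusted p = 4.2e-07, and 0.083 with an estimated correlation). An example was TYMS (-1.84 ± 0.06). MYC-activated genes were lower for 31 of 35 and higher for 3, also adjusted over the list alone (median -0.91, camera adjusted p = 1.1e-07, and 0.055 with an estimated correlation). Examples were DDX21 (-2.18 ± 0.07) and TCOF1 (-1.97 ± 0.07). Oxidative phosphorylation genes fell, with 19 of 27 lower and 5 higher, also adjusted over the list alone (camera adjusted p = 0.015, and 0.16 with an estimated correlation). An example was CYC1 (-0.75 ± 0.05).

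Class I presentation genes rose in SUM159PT with MYC siRNA, with 16 of 20 higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.0047, and 0.16 with an estimated correlation). Examples were HLA-B (0.91 ± 0.04) and NLRC5, their transactivator (0.77 ± 0.06). Interferon-stimulated genes rose, with 23 of 38 higher and 7 lower, also adjusted over the list alone (camera adjusted p = 0.015, and 0.16 with an estimated correlation). Examples were MX2 (2.04 ± 0.3) and ISG15 (1.55 ± 0.1). Immune checkpoint ligands rose, with 7 of 10 higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.022, and 0.29 with an estimated correlation). Examples were LGALS9 (2.82 ± 0.28) and CD276 (1.97 ± 0.04). Mesenchymal markers were higher for 14 of 18 and lower for none, also adjusted over the list alone (camera adjusted p = 0.00016, and 0.12 with an estimated correlation), and all 6 fibroblast markers were higher, also adjusted over the list alone (camera adjusted p = 0.0013, and 0.16 with an estimated correlation). PDGFRB rose by 3.37 ± 0.11, COL1A1 by 2.84 ± 0.03 and COL5A1 by 2.58 ± 0.03. Targets of p53 were higher for 12 of 17 and lower for 2, also adjusted over the list alone, led by the cell cycle inhibitor CDKN1A (1.64 ± 0.04). That call (camera adjusted p = 0.023) became 0.13 after GC correction (adjusted p = 0.16 with an estimated correlation). The other 12 of 23 lists did not pass, at adjusted p from 0.17 to 0.99.

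Lowest among the named genes in SUM159PT with MYC siRNA were HMGN5 (-3.66 ± 0.13), RMI2 (-3.64 ± 0.19) and NPM3 (-3.25 ± 0.14), and the highest were WNT7B (4.83 ± 0.19), P2RX1 (4.8 ± 0.14) and COL7A1 (4.1 ± 0.05). Both siRNAs called 9558 genes in the same direction and 0 in opposite directions, against 1735 higher plus 1668 lower for independent lists. The same reservation about shared controls applies. Of 8334 genes called in both human lines with MYC siRNA, 95% changed in the same direction (Fisher's exact test, log2 odds ratio 8.54), with 3957 higher in both against 1775 for independent lists. Against the Tax-R comparison of the same line, jointly called genes had the same direction in 39.2% of 5979 cases in MDA-MB-436 (Fisher's exact test, p = 2.98e-69) and 50.4% of 5191 in SUM159PT (p = 0.714). Among the 500 genes of lowest p in each MDA-MB-436 comparison that share turned to 62.5% (Fisher's exact test, p = 0.306), and in SUM159PT it was 44.9% after GC correction (p = 1.48e-15) and 54.1% after quantile normalization (p = 4.84e-08).

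In mouse 4T1 cells, the libraries labelled MYC siRNA showed smaller changes: Sting1, Ccl5, interferon-stimulated and class I genes rose, and MYC-activated genes fell. Myc was at 2390, 2595 and 2433 in the control libraries, 2220, 2407 and 2232 with siMYC1 and 2340, 2366 and 2344 with siMYC2 (-0.09 ± 0.04, limma adjusted p = 0.0683, but -0.17 and 0.00225 after quantile normalization). Sting1 rose from 127.9 ± 10.05 (n = 3) to 169.5 ± 18.49 and 168.2 ± 14.15 (n = 3 each, 0.4 ± 0.09, limma adjusted p = 0.00106). Ccl5 rose by 0.42 ± 0.09, and Cxcl10 (0.17 ± 0.17, limma adjusted p = 0.44) and Cgas (0.11 ± 0.09, limma adjusted p = 0.316) did not pass. Cxcl11 was below the filter, with group means of 2.422 ± 1.73, 2.021 ± 1.775 and 4.757 ± 4.005. Of 14081 genes tested, 3473 were higher and 3028 lower, of which 155 and 76 changed at least 2-fold.

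Interferon-stimulated genes were higher for 28 of 41 in 4T1, 31 adjusted over the list alone, and lower for none (median 0.45, camera adjusted p = 3.6e-09, and 0.18 with an estimated correlation). Examples were Isg15 (1.31 ± 0.1) and Usp18 (1.18 ± 0.12). Class I presentation genes were higher for 18 of 19 and lower for none, also adjusted over the list alone (camera adjusted p = 2.6e-07, and 0.15 with an estimated correlation). Examples were the immunoproteasome subunit Psmb8 (0.74 ± 0.06) and B2m (0.55 ± 0.04). Immune checkpoint ligands rose, with 7 of 9 higher and none lower, also adjusted over the list alone (camera adjusted p = 0.0023, and 0.15 with an estimated correlation). An example was Lgals9 (1.09 ± 0.07). MYC-activated genes were lower for 29 of 35 and higher for 2, or 30 and 2 adjusted over the list alone (median -0.36, camera adjusted p = 8.5e-10, and 0.18 with an estimated correlation). Examples were Rcl1 (-0.77 ± 0.07) and Cad (-0.61 ± 0.04). Nucleotide synthesis genes fell, with 13 of 21 lower and 2 higher, also adjusted over the list alone (camera adjusted p = 0.00053, and 0.18 with an estimated correlation). Examples were the folate enzymes Mthfd2 (-0.98 ± 0.07) and Shmt2 (-0.8 ± 0.05). Genes of the unfolded protein and amino acid response fell, with 13 of 19 lower and 4 higher, also adjusted over the list alone (camera adjusted p = 0.01, and 0.39 with an estimated correlation). Examples were Trib3 (-1.55 ± 0.11) and the cystine transporter Slc7a11 (-1.53 ± 0.12).

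E2F and replication genes rose in 4T1, with 15 of 26 higher and 4 lower, or 16 and 4 adjusted over the list alone (camera adjusted p = 0.01, and 0.62 with an estimated correlation). Examples were Cdc6 (0.65 ± 0.09) and E2f1 (0.6 ± 0.06). Tubulins and microtubule regulators were higher for 12 of 16 and lower for 1, also adjusted over the list alone (camera adjusted p = 4.7e-05, and 0.18 with an estimated correlation). An example was Tuba1a (0.87 ± 0.05). Cholesterol synthesis genes were higher for 14 of 17, 15 adjusted over the list alone, and lower for none (camera adjusted p = 8.2e-05, and 0.25 with an estimated correlation). An example was Insig1 (0.93 ± 0.07). Mesenchymal markers rose, with 8 of 13 higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.00079, and 0.18 with an estimated correlation). Examples were Fn1 (1.05 ± 0.04) and Vim (1.02 ± 0.04). The lowest named genes were the chemokine Ccl20 (-1.7 ± 0.14), Trib3 and Slc7a11, and the highest were the matrix protein Tnc (3.25 ± 0.07) and the interferon-inducible GTPases Tgtp2 (2.36 ± 0.18) and Tgtp1 (2.14 ± 0.15), which are near-identical and can share reads. The other 14 of 24 lists did not pass, at adjusted p from 0.055 to 0.98. Both siRNAs called 4733 genes in the same direction and 0 in opposite directions, against 672 higher plus 447 lower for independent lists. Controls were again shared.

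STING sgRNA in MDA-MB-436 left less STING1, sharply lower chemokines and interferon-stimulated genes, and 4 of 7 RNA sensors lower. STING1 was at 182.5 and 157.8 in the mock libraries, 55.1 and 41.7 in C1 and 44 and 46 in C2 (-1.85 ± 0.15, limma adjusted p = 3.69e-11). CCL5 fell from 405.3 ± 11.95 (n = 2) to 3 reads in C1, 262-fold lower with an interval of 89.5 to 1.28e+03, and 1 read in C2, 792-fold lower with an interval of 142 to 3.13e+04. CXCL10 fell from 239 ± 3.995 to 15.84 ± 0.2738 and 22.22 ± 3.93 (n = 2 each, -3.61 ± 0.18, limma adjusted p = 6.05e-16), and CXCL11 was lower (-2.52 ± 0.14). CGAS rose by 0.43 ± 0.06 and MYC by 0.1 ± 0.04 (limma adjusted p = 0.0365). That MYC call was lost after quantile normalization (0.06, adjusted p = 0.196), with DESeq2 (0.186), without the filter (0.0845) and with C2 alone (0.133).

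Interferon-stimulated genes were lower for 37 of 41 in MDA-MB-436 with STING sgRNA and higher for 1, or 39 and 1 adjusted over the list alone (median -1.09, camera adjusted p = 4.3e-19, and 0.037 with an estimated correlation). OASL (-7.09 ± 0.24), IFIT2 (-5.6 ± 0.23), HERC5 (-4.77 ± 0.3) and IFIT1 (-4.04 ± 0.21) fell most. Of 5 T cell-attracting chemokines 4 fell and none rose, also adjusted over the list alone (median -3.61, camera adjusted p = 0.00061, and 0.3 with an estimated correlation). RNA sensors fell, with 4 of 7 lower and none higher, also adjusted over the list alone (camera adjusted p = 0.022, and 0.44 with an estimated correlation). Examples were RIGI (-2.09 ± 0.12), DHX58 (-1.72 ± 0.18) and IFIH1 (-0.98 ± 0.12). Inflammatory NF-kB targets fell, with 9 of 19 lower and 2 higher, also adjusted over the list alone (camera adjusted p = 0.035, and 0.44 with an estimated correlation). Examples were PTGS2, the inducible cyclooxygenase (-0.99 ± 0.11), and SOD2 (-0.79 ± 0.03), while IL1B rose by 1.11 ± 0.21.

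Class I presentation genes were lower for 14 of 20 and higher for 4, also adjusted over the list alone, such as HLA-F (-0.85 ± 0.1) and HLA-B (-0.45 ± 0.04), at a camera adjusted p of 0.025 that became 0.094 after GC correction (adjusted p = 0.44 with an estimated correlation). Oxidative phosphorylation genes fell, with 12 of 27 lower and 2 higher, also adjusted over the list alone (camera adjusted p = 0.044, and 0.44 with an estimated correlation). An example was NDUFA1 (-0.71 ± 0.11). MYC-activated genes were higher for 18 of 35 and lower for 6, also adjusted over the list alone, with DDX21 (0.58 ± 0.03) higher and EIF4A1 (-0.48 ± 0.12, DESeq2 adjusted p = 0.0587) lower, at a camera adjusted p of 0.041 that became 0.18 after quantile normalization (adjusted p = 0.44 with an estimated correlation). Mitosis genes were higher for 14 of 24 and lower for 2, or 14 and 4 adjusted over the list alone, such as CENPE (0.6 ± 0.05), at a camera adjusted p of 0.025 that became 0.14 after quantile normalization and 0.15 after GC correction (adjusted p = 0.44 with an estimated correlation). The other 15 of 23 lists did not pass, at adjusted p from 0.18 to 0.97. The highest named genes were ZNF788 (2.94 ± 0.2), the kinesin KIF13A (2.58 ± 0.18) and OSBP2 (2.19 ± 0.15).

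Of 15305 genes tested in MDA-MB-436 with STING sgRNA, 3793 were higher and 3523 lower, of which 136 and 356 changed at least 2-fold. Fold changes followed the GC content of transcripts (Spearman's rho -0.55 across 12963 genes), and after GC correction 3701 genes were higher and 2024 lower. DESeq2 on the recovered reads called 3971. C1 and C2 shared 4795 calls in the same direction and 0 in opposite directions, against 697 higher plus 578 lower for independent lists. The mock libraries were shared.

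In SUM159PT, STING sgRNA also lowered STING1, but the chemokines were near the floor already in mock cells and the interferon-stimulated list did not pass. STING1 was at 261.3 and 229.4 in the mock libraries, 94.9 and 114.3 in C1 and 100.8 and 92.7 in C2 (-1.28 ± 0.11, limma adjusted p = 1.29e-12). CCL5 was at 5.261 ± 0.6524 in mock (n = 2) and had no read in C1 or C2, at least 3.51-fold and 3.41-fold lower but untested. CXCL11 was at 6.7 ± 1.384 in mock and had 1 read in each sgRNA group. It was 12.8-fold lower in C1 (interval 1.95 to 541) and 13-fold in C2 (1.98 to 551), untested. CXCL10 was at 3.341 ± 3.367. Interferon-stimulated genes had 9 of 36 higher and 15 lower (camera adjusted p = 0.24). CGAS rose by 0.3 ± 0.08, a call lost with DESeq2 (adjusted p = 0.0893) and without the filter (0.0648). MYC did not pass (0.08 ± 0.04, limma adjusted p = 0.104), but did after GC correction (0.17, 0.000241).

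Glycolysis and hypoxia genes fell in SUM159PT with STING sgRNA, with 19 of 25 lower and none higher, also adjusted over the list alone (camera adjusted p = 1.2e-06, and 0.35 with an estimated correlation). Examples were CA9 (-2.98 ± 0.21), PFKFB4 (-1.51 ± 0.16) and the glucose transporter SLC2A3 (-0.94 ± 0.07). Inflammatory NF-kB targets fell, with 10 of 14 lower and 1 higher, or 11 and 1 adjusted over the list alone (camera adjusted p = 0.00064, and 0.25 with an estimated correlation). Examples were CXCL8, which attracts neutrophils (-1.24 ± 0.14), and LIF (-1.19 ± 0.32), while PTGS2 rose by 1.16 ± 0.3. The calls of LIF and PTGS2 were lost with DESeq2 (adjusted p = 0.104 and 0.137) and without the filter (0.0779 and 0.138), and that of LIF with C1 alone (-0.71, 0.171). MYC-activated genes were lower for 25 of 35 and higher for 1, or 26 and 1 adjusted over the list alone (median -0.19, camera adjusted p = 7.2e-05, and 0.25 with an estimated correlation). Examples were WDR74 (-0.7 ± 0.07) and BOP1 (-0.46 ± 0.05). Mitosis genes were higher for 15 of 24 and lower for 1, or 16 and 1 adjusted over the list alone (camera adjusted p = 0.0016, and 0.35 with an estimated correlation). An example was KIF20A (0.56 ± 0.04), while AURKB fell by 0.38 ± 0.06. Tubulins and microtubule regulators were higher for 9 of 16 and lower for none, also adjusted over the list alone (camera adjusted p = 0.0018, and 0.25 with an estimated correlation). Examples were TUBA1A (0.83 ± 0.05) and MAP1B (0.58 ± 0.05). Basal markers were higher for 3 of 6 and lower for none, also adjusted over the list alone, TP63 by 3.03 ± 0.17 and KRT5 by 0.85 ± 0.08 (camera adjusted p = 0.01, and 0.31 with an estimated correlation). The other 17 of 23 lists did not pass, at adjusted p from 0.072 to 0.93.

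Among called genes with a symbol and a mean of at least 50, the lowest in SUM159PT with STING sgRNA were TIMP3, a protease inhibitor with no read in C1 or C2 and at least 248-fold and 241-fold lower, the keratin KRT81 (-4.37 ± 0.24) and COL6A3 (-4.25 ± 0.11). The highest were FAM213A (81.5-fold in C1 with an interval of 27.6 to 398 and 66-fold in C2 with an interval of 22.2 to 323), CNTNAP2 (4.7 ± 0.19) and the small heat shock protein CRYAB (4.09 ± 0.1). Of 15168 genes tested, 2925 were higher and 3002 lower, of which 279 and 252 changed at least 2-fold, and DESeq2 on the recovered reads called 2864. C1 alone called 3487 genes and C2 alone 6722, and the 2 groups differed for 3025 genes. They shared 2882 calls in the same direction and 13 in opposite directions, against 395 higher plus 376 lower for independent lists. Of 3401 genes called in both lines with STING sgRNA, 78.6% changed in the same direction (Fisher's exact test, p = 2.2e-257), but the share was 64.6% after GC correction (p = 3.26e-46) and 57.1% among the 500 genes of lowest p in each (p = 0.0824).

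**Figure D2:**
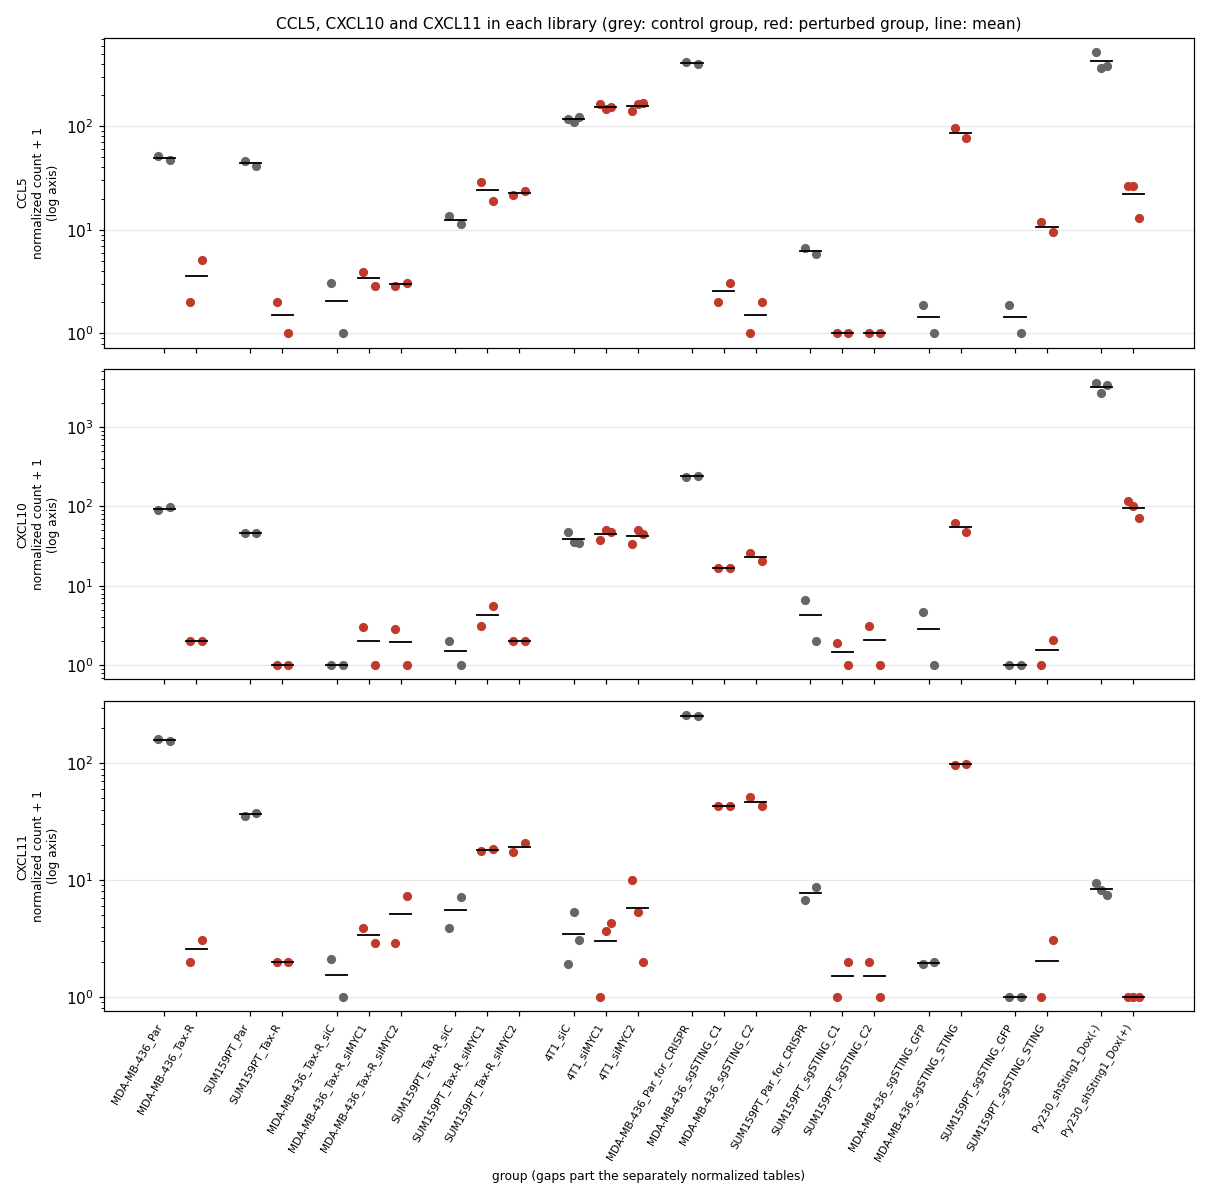
Normalized counts plus 1 (log axis) of CCL5, CXCL10 and CXCL11 in every library, with control groups in grey, perturbed groups in red and a line at each group mean. In MDA-MB-436, CCL5 was at a mean of 405.3 in mock cells and at most 1.544 in the STING sgRNA groups, and at 85.43 with the STING ORF, and levels are not comparable between tables that were normalized separately.

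Adding a STING ORF to STING sgRNA cells of MDA-MB-436 was followed by higher STING1, chemokines, inflammatory cytokines and interferon-stimulated genes. STING1 was at 32.1 and 21 in the GFP libraries and 613.9 and 579.4 in the STING ORF libraries (4.47 ± 0.16, limma adjusted p = 2.9e-21), where the counts do not separate endogenous from introduced transcripts. CCL5 had 1 read with GFP and was at 85.43 ± 13.59 with STING (n = 2), 186-fold higher with an interval of 32.9 to 7.4e+03. CXCL11 had 2 reads with GFP and was at 97.17 ± 1.427, 104-fold higher with an interval of 28.3 to 864, and CXCL10 rose by 4.66 ± 0.5. CGAS rose by 0.41 ± 0.09 (0.0623 without the filter), and MYC did not pass (-0.14 ± 0.08, limma adjusted p = 0.181, 0.0452 with the replicate number as a block).

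Inflammatory NF-kB targets rose in MDA-MB-436 with the STING ORF, with 16 of 19 higher and none lower, also adjusted over the list alone (median 1.13, camera adjusted p = 3.5e-13, and 0.27 with an estimated correlation). CXCL8 rose from 303.7 ± 41.31 to 2792 ± 187.4 (n = 2 each, 3.2 ± 0.09), IL6 by 2.89 ± 0.11, PTGS2 by 2.89 ± 0.2 and the cytokine IL1A by 2.76 ± 0.2. Interferon-stimulated genes rose, with 18 of 39 higher and 5 lower, or 19 and 5 adjusted over the list alone, led by OASL (6.61 ± 0.27), IFIT1 (5.36 ± 0.24), IFIT2 (5.14 ± 0.19) and HERC5 (4.88 ± 0.31) (median 0.35, camera adjusted p = 5.4e-07, and 0.27 with an estimated correlation). Of 5 T cell-attracting chemokines 4 rose and none fell, also adjusted over the list alone, CCL20 by 2.5 ± 0.45, a call lost without the filter (0.0613) (camera adjusted p = 0.0011, and 0.41 with an estimated correlation). RNA sensors were higher for 3 of 7 and lower for none, also adjusted over the list alone, RIGI by 1.95 ± 0.16 and IFIH1 by 1.25 ± 0.16 (camera adjusted p = 0.024, and 0.41 with an estimated correlation). The cGAS-STING list, which includes STING1 itself, was higher for 4 of 12 and lower for none, also adjusted over the list alone, with the kinase TBK1 (0.32 ± 0.09) among them (camera adjusted p = 0.024, and 0.41 with an estimated correlation). TBK1 was not called after GC correction (0.16, adjusted p = 0.165), with DESeq2 (0.117) or without the filter (0.0965). MYC-activated genes were lower for 13 of 35, 16 adjusted over the list alone, and higher for none (median -0.16, camera adjusted p = 0.00077, and 0.35 with an estimated correlation). An example was PES1 (-0.6 ± 0.08). Oxidative phosphorylation genes were lower for 9 of 27, 10 adjusted over the list alone, and higher for none, such as COX5A (-0.53 ± 0.09), at a camera adjusted p of 0.024 that became 0.071 after quantile normalization (adjusted p = 0.59 with an estimated correlation). The other 16 of 23 lists did not pass, at adjusted p from 0.14 to 0.67.

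The lowest named genes with the STING ORF in MDA-MB-436 were the complement factor CFI (-1.69 ± 0.22), the pseudogene SPCS2P4, which can share reads with its parent gene (-1.61 ± 0.19), and CD9 (-1.44 ± 0.2). Of 14851 genes tested, 1366 were higher and 1768 lower, of which 193 and 116 changed at least 2-fold. Fewer genes were called by DESeq2 (1037), without the filter on low values (328), without GFP replicate 1 (1707) or without STING ORF replicate 2 (1247). Of 2013 genes called in both the STING sgRNA and the STING ORF comparison of this line, 81.7% changed in the same direction (Fisher's exact test, p = 3.21e-185), but 56.2% after GC correction (p = 1.31e-05) and 53% among the 500 genes of lowest p in each (p = 0.0433).

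In SUM159PT, the STING ORF raised STING1 and inflammatory genes, and hypoxia genes rose while basal keratins and cholesterol synthesis genes fell. STING1 was at 65.4 and 81.1 in the GFP libraries and 1599 and 1455 in the STING ORF libraries (4.37 ± 0.12, limma adjusted p = 2.89e-21). CCL5 had 1 read with GFP and was at 9.756 ± 1.731 with STING (n = 2), 22.4-fold higher (interval 3.56 to 930) but untested. CXCL10 and CXCL11 had no read with GFP and means of 0.5333 ± 0.7541 and 1.067 ± 1.508 with STING. CGAS rose by 0.29 ± 0.11 (limma adjusted p = 0.0448), a call lost after quantile normalization (0.0678), with DESeq2 (0.258) and without the filter (0.105), and MYC did not pass (-0.07 ± 0.06, limma adjusted p = 0.457).

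Inflammatory NF-kB targets rose in SUM159PT with the STING ORF, with 13 of 15 higher, 14 adjusted over the list alone, and none lower (median 0.76, camera adjusted p = 5.9e-10, and 0.3 with an estimated correlation). Examples were CXCL8 (2.59 ± 0.15), BIRC3 (1.95 ± 0.15) and TNFAIP3, which restrains NF-kB (1.83 ± 0.13). Interferon-stimulated genes rose, with 8 of 35 higher and 1 lower, or 10 and 1 adjusted over the list alone, led by OASL (3.66 ± 0.39) and IFIT1 (2.59 ± 0.33) (camera adjusted p = 0.01, and 0.3 with an estimated correlation). The cGAS-STING list was higher for 4 of 12 and lower for none, or 4 and 1 adjusted over the list alone, with the DNA sensor IFI16 (0.29 ± 0.09) among those higher (camera adjusted p = 0.022, and 0.3 with an estimated correlation). The IFI16 call was lost after quantile normalization (0.0613), with DESeq2 (0.0823) and without the filter (0.198). Glycolysis and hypoxia genes were higher for 17 of 25, 20 adjusted over the list alone, and lower for none (camera adjusted p = 1.3e-08, and 0.3 with an estimated correlation). Examples were CA9 (4 ± 0.12), ENO2 (1.28 ± 0.11) and BNIP3 (1.21 ± 0.08). Genes of the unfolded protein and amino acid response were higher for 9 of 18 and lower for none, also adjusted over the list alone (camera adjusted p = 0.019, and 0.3 with an estimated correlation). An example was PSAT1 of serine synthesis (0.64 ± 0.08). Mitosis genes were higher for 11 of 24 and lower for none, also adjusted over the list alone (camera adjusted p = 0.008, and 0.44 with an estimated correlation). An example was AURKB (0.64 ± 0.09).

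Basal keratins and basal markers were lower for 5 of 6 in SUM159PT with the STING ORF and higher for 1, also adjusted over the list alone (camera adjusted p = 0.0092, and 0.3 with an estimated correlation). Examples were KRT6A (-1.55 ± 0.18), KRT5 (-1.54 ± 0.18) and TP63 (-1.53 ± 0.2). Cholesterol synthesis genes fell, with 10 of 18 lower and 2 higher, or 13 and 3 adjusted over the list alone (camera adjusted p = 0.0067, and 0.3 with an estimated correlation). Examples were INSIG1 (-0.68 ± 0.1) and HMGCS1 (-0.65 ± 0.08). Epithelial markers were lower for 3 of 4, all 4 adjusted over the list alone (camera adjusted p = 0.015, and 0.3 with an estimated correlation). An example was the desmosome protein DSP (-0.82 ± 0.09). The calls of 3 lists were lost after quantile normalization. They were class I presentation (8 of 20 higher and 2 lower, 11 and 2 adjusted over the list alone, camera adjusted p = 0.021 and 0.081 after quantile normalization), MYC-activated genes (14 of 35 higher and 1 lower, 15 and 1 adjusted over the list alone, 0.01 and 0.081) and oxidative phosphorylation (7 of 27 higher and none lower, 8 and 0 adjusted over the list alone, 0.038 and 0.17). For each of these, adjusted p = 0.3 with an estimated correlation, and HLA-B (0.33 ± 0.07), TFRC, the transferrin receptor (0.69 ± 0.06), and NDUFB3 (0.44 ± 0.1) were examples. The other 11 of 23 lists did not pass, at adjusted p from 0.053 to 0.97.

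Called genes with a mean of at least 50 that were lowest in SUM159PT with the STING ORF were ISLR (-2.59 ± 0.19), the apolipoprotein APOE (-2.43 ± 0.15) and OLFML2A (-2.12 ± 0.21), and the highest besides STING1 and CA9 was OLR1, a receptor for oxidized lipoprotein (2.92 ± 0.22). Of 14915 genes tested, 1964 were higher and 1911 lower, of which 204 and 279 changed at least 2-fold. Fewer genes were called by DESeq2 (1472), without the filter on low values (884), without GFP replicate 1 (1257) or without GFP replicate 2 (1489). Of 1205 genes called in both lines with the STING ORF, 87.5% changed in the same direction (Fisher's exact test, p = 8.28e-166), and 74.8% after GC correction (p = 1.69e-71). Of 1774 called with both STING sgRNA and STING ORF in SUM159PT, 40.2% had the same direction (Fisher's exact test, p = 2.46e-16). That share was 26.2% after GC correction (Fisher's exact test, p = 1.93e-117) and 12.1% among the 500 genes of lowest p in each (p = 3.91e-17).

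Doxycycline given to Py230 cells with a Sting1 shRNA was followed by far lower Sting1 and lower interferon-stimulated, class I presentation and mitosis genes. Sting1 was at 841.2, 768.3 and 885.7 with vehicle and 48.3, 47.5 and 42.9 with doxycycline (-4.14 ± 0.09, limma adjusted p = 4e-22). Cxcl10 fell from 3186 ± 455.9 to 95.79 ± 22.56 (n = 3 each, -5.06 ± 0.11, limma adjusted p = 5.53e-22) and Ccl5 from 422.3 ± 87.36 to 20.96 ± 7.87 (-4.33 ± 0.2). Cxcl11 was at 7.363 ± 1.081 with vehicle and had no read with doxycycline, at least 7.45-fold lower but untested. Cgas fell by 1.05 ± 0.13 and Myc from 3108 ± 293.1 to 994 ± 28.3 (-1.64 ± 0.05, limma adjusted p = 1.41e-18). No group received doxycycline without the shRNA, so drug and shRNA effects cannot be separated.

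Interferon-stimulated genes were lower for 40 of 42 in Py230 and higher for 1, also adjusted over the list alone (median -2.53, camera adjusted p = 4.6e-16, and 0.32 with an estimated correlation). Examples were Mx1 (-6.22 ± 0.09), Oas2 (-5.77 ± 0.09) and Ifit2 (-4.77 ± 0.08). Class I presentation genes were lower for 17 of 19 and higher for 1, also adjusted over the list alone (camera adjusted p = 9e-08, and 0.32 with an estimated correlation). Examples were Psmb9 (-4.86 ± 0.15), Nlrc5 (-4.3 ± 0.09) and H2-Q4 (-4.16 ± 0.07). RNA sensors fell, with 6 of 8 lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.0071, and 0.39 with an estimated correlation). Examples were Dhx58 (-3.06 ± 0.07) and Zbp1 (-2.98 ± 0.06). Inflammatory NF-kB targets fell, with 9 of 13 lower and 3 higher, also adjusted over the list alone (camera adjusted p = 0.036, 0.059 with the replicate number as a block, and 0.32 with an estimated correlation). Examples were the chemokine Ccl2 (-4.02 ± 0.24) and Relb (-1.47 ± 0.07). Immune checkpoint ligands fell, with 6 of 8 lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.044, 0.076 with the block, and 0.32 with an estimated correlation). Examples were Cd274, which encodes PD-L1 (-4.51 ± 0.14), and Lgals9 (-4.02 ± 0.08), while Vtcn1 rose by 0.94 ± 0.14.

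All 24 mitosis genes fell in Py230, also adjusted over the list alone (median -1.16, camera adjusted p = 1.9e-09, and 0.32 with an estimated correlation). Examples were Cenpe (-1.93 ± 0.08) and Mki67 (-1.67 ± 0.07). MYC-activated genes were lower for 33 of 35 and higher for 1, or 34 and 1 adjusted over the list alone (median -0.61, camera adjusted p = 1.9e-09, and 0.32 with an estimated correlation). Examples were Rcl1 (-1.75 ± 0.08) and Tcof1 (-1.47 ± 0.05). Genes of the unfolded protein and amino acid response were lower for 18 of 19 and higher for 1, also adjusted over the list alone (camera adjusted p = 5.3e-06, and 0.32 with an estimated correlation). Examples were Psat1 (-2.23 ± 0.06) and Chac1 (-2.2 ± 0.11). Nucleotide synthesis genes fell, with 14 of 21 lower and 3 higher, also adjusted over the list alone (camera adjusted p = 0.025, and 0.32 with an estimated correlation). An example was Mthfd2 (-2.17 ± 0.07). E2F and replication genes fell, with 16 of 26 lower and 6 higher, also adjusted over the list alone (camera adjusted p = 0.04, 0.064 with the block, and 0.65 with an estimated correlation). An example was the cyclin Ccne1 (-2.09 ± 0.16).

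The lowest named genes in Py230 were the interferon-inducible Ifi206, with no read under doxycycline and at least 366-fold lower, Ifi213, 214-fold lower on 3 reads with an interval of 73 to 1.04e+03, and Ifi47 (-6.5 ± 0.36). The highest were the keratin Krt42 (6.96 ± 0.22), Gmnc, 223-fold higher on 2 vehicle reads with an interval of 61.5 to 1.85e+03, and the kinesin Kif26a (5.81 ± 0.13). Of 14461 genes tested, 4736 were higher and 5075 lower, of which 937 and 1134 changed at least 2-fold. The T cell-attracting chemokines, with 4 of 5 lower, did not pass as a list (camera adjusted p = 0.089) and neither did 13 others of 24, at adjusted p up to 0.99.

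**Figure D3:**
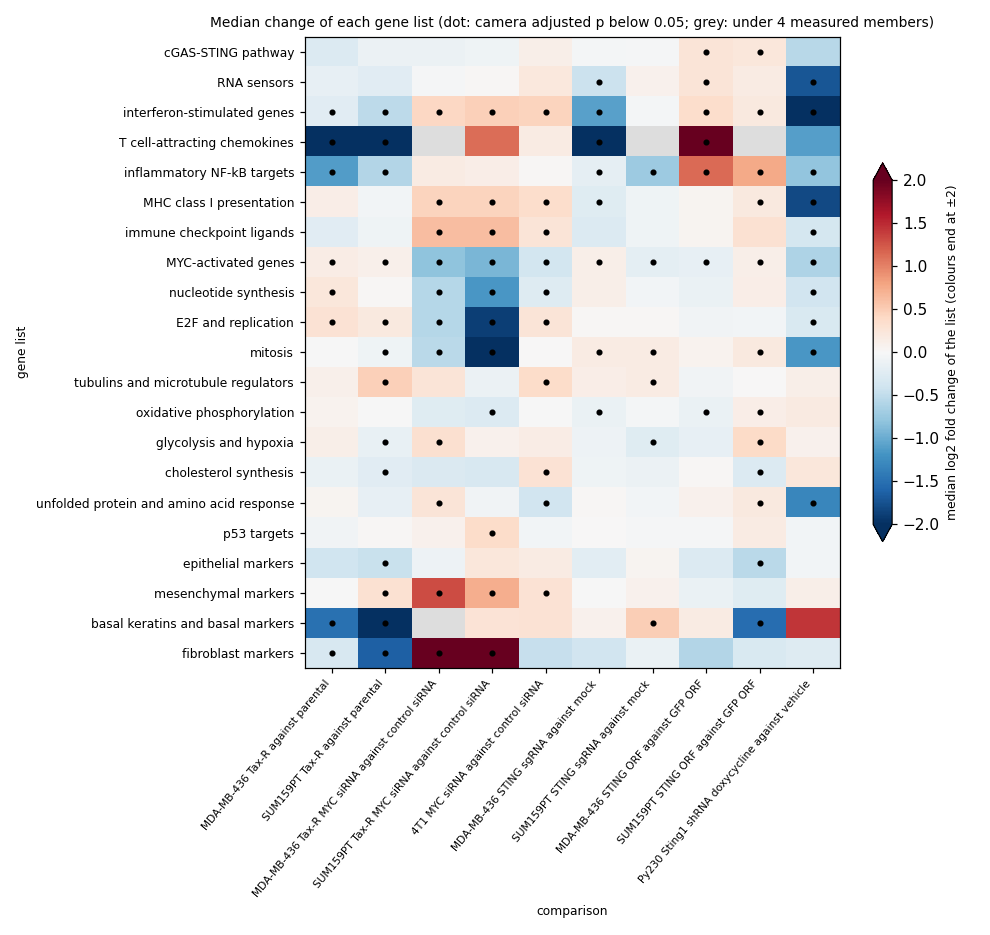
Median log2 fold change (colour, ending at 2 in either direction) of 21 of the fixed gene lists (vertical axis) in each comparison (horizontal axis), with a dot where the camera adjusted p was below 0.05 and grey where fewer than 4 members were measured. The inflammatory NF-kB list passed in both STING ORF comparisons with medians of 1.13 and 0.76, and the interferon-stimulated list passed in all comparisons except SUM159PT STING sgRNA.

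Several lists did not pass with the planned camera test in any comparison. DNA methylation and chromatin repressors were tested in all 10 comparisons, at adjusted p from 0.29 to 0.97, and drug efflux transporters likewise, at 0.14 to 0.74, although ABCB1 changed in the Tax-R comparisons. The efflux list did pass with the STING ORF in MDA-MB-436 after GC correction (median 0.19, adjusted p = 0.042). With fry several of these lists passed, efflux in both Tax-R comparisons among them (9e-04 and 0.0035). Myeloid markers were measured in 3 comparisons (adjusted p = 0.13, 0.78 and 0.99), endothelial markers in SUM159PT Tax-R only (0.14), mitochondrially encoded transcripts in 3 (0.45, 0.65 and 0.41) and class II presentation genes in 2 (0.88 and 0.072), of which the SUM159PT STING ORF comparison passed after GC correction (median -0.23, adjusted p = 0.048). T cell markers had fewer than 4 measured members in every table.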

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

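The tests of weak suppression, shared cell populations and GC content were chosen after the results were seen, the other sample splits before.

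List medians went in opposite directions under the same contrast in 6 cases, all past the camera threshold on both sides, and the difference itself was not tested. For E2F and replication with MYC siRNA, the median in MDA-MB-436 minus that in 4T1 was -0.82 (-0.57 and 0.25), and SUM159PT minus 4T1 was -2.14 (-1.89 and 0.25). The unfolded protein and amino acid response with MYC siRNA differed by 0.64 (0.26 in MDA-MB-436, -0.38 in 4T1). MYC-activated genes with STING sgRNA differed by 0.3 (0.11 in MDA-MB-436, -0.19 in SUM159PT), and with the STING ORF by -0.27 (-0.16 and 0.11). Oxidative phosphorylation with the STING ORF differed by -0.26 (-0.13 and 0.13). After quantile normalization the lists of MYC-activated genes in MDA-MB-436 STING sgRNA (adjusted p = 0.18) and SUM159PT STING ORF (0.081), and oxidative phosphorylation in both ORF comparisons (0.071 and 0.17), no longer passed. After GC correction all human sides still passed, with MYC-activated medians of 0.18 and -0.11 for STING sgRNA and -0.15 and 0.18 for the ORF, in MDA-MB-436 and SUM159PT.

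The MYC transcript changed little with MYC siRNA in MDA-MB-436 (-0.09) and 4T1 (-0.09). MYC-activated genes fell, with medians of -0.8 and -0.36. They also fell with SUM159PT STING sgRNA (-0.19), where MYC did not, so their fall cannot show MYC suppression. An off-target effect of 1 siRNA would be seen with 1 of them, while 8878 genes in MDA-MB-436 and 4733 in 4T1 were called in the same direction with both, though against shared controls. Failed suppression, effects common to both siRNAs and a lower MYC protein without a lower transcript may each remain, untested.

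Tax-R changes were shared by both human lines. Were both names 1 population, genes that separate the lines in mock and control siRNA libraries would not do so. All 35 such genes kept their direction between lines (median log2 difference 2.29 in parental, 1.74 in Tax-R libraries). This argues only against full identity. Between Tax-R lines 46 genes differed at least 4-fold, against 352 with control siRNA. Partial mixing and a shared Tax-R state may remain, untested.

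Fold changes followed transcript GC content in all 4 human STING comparisons (Spearman's rho across genes -0.55 and -0.38 with STING sgRNA, -0.51 and -0.32 with the STING ORF, in MDA-MB-436 and SUM159PT) and with MYC siRNA (0.23 and 0.34). GC content as the whole cause of the lower interferon-stimulated genes with STING sgRNA in MDA-MB-436 is argued against by their median of -0.84 after correction (-1.09 before). For genes called with both STING sgRNA and STING ORF in that line, the share with the same direction fell from 81.7% to 56.2% after correction, so a GC trend may account for much of that sharing. Between lines the share fell from 78.6% to 64.6% with STING sgRNA and from 87.5% to 74.8% with the STING ORF. Libraries of 1 group also differed along GC content, by a rho of up to 0.54 and 0.41 in the SUM159PT ORF and MYC siRNA tables, more than between their groups, but of up to 0.13 in the SUM159PT sgRNA table and 0.27, 0.38 and 0.15 in the MDA-MB-436 sgRNA, ORF and siRNA tables, less than between groups, so the origin of the trend stays open.

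In 4T1, 3 of 100 splits of the 9 libraries, the real one included, reached the real 6501 genes. This excludes chance at 0.05 only for independent libraries. The other 2 kept the real controls (highest 6627), and moving controls gave at most 2949. The 10 splits for Py230 (real 9811, highest other 0) and for each 4T1 siRNA alone (real 5137 and 5932, highest other 0 in each) are too few for a share under 0.05, and 1 split of the 10, the real one, reached the real value in each.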

How the results depend on the processing

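The GC correction and the MDA-MB-436 Tax-R libraries counted as 1 were chosen after the data were seen, the other alternatives before. Causes were not tested unless named.

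Gene counts stayed within 1.5 times of the reported value under a pseudocount of 4, quantile normalization, the replicate block and edgeR in all 10 comparisons. With replicate number as a block the STING ORF gave 4400 genes in MDA-MB-436 and 5225 in SUM159PT (3134 and 3875 without), the largest moves, and libraries of the same number correlated by -0.09 to 0.11 over 44 pairs, highest in SUM159PT ORF. Requiring a 2-fold change left 2293 and 2013 genes for Tax-R in MDA-MB-436 and SUM159PT, 2132, 2972 and 231 for MYC siRNA in MDA-MB-436, SUM159PT and 4T1, 492 and 531 for STING sgRNA, 309 and 483 for the STING ORF, and 2071 in Py230, fewer by construction. DESeq2 gave 4209 for SUM159PT Tax-R, 3971 and 2864 for STING sgRNA, and 1037 and 1472 for the STING ORF in MDA-MB-436 and SUM159PT. Without the filter the ORF counts were 328 and 884. C1 alone gave 3487 in SUM159PT and C2 alone 6722, against the same mock libraries. Both groups were of the same size, so fewer samples do not explain the lower count of C1. After GC correction the SUM159PT ORF comparison had 2964 genes higher and 2115 lower, against 1964 and 1911, and MDA-MB-436 STING sgRNA 3701 and 2024, against 3793 and 3523.

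Leaving out 1 library gave 8081 to 9113 and 6616 to 7253 genes for Tax-R, 9460 to 10106, 10049 to 10584 and 5494 to 6535 for MYC siRNA, 4980 to 7260 and 4150 to 5460 for STING sgRNA, 1247 to 3610 and 1257 to 5463 for the STING ORF, in the order of lines above, and 9173 to 9609 in Py230. A lone sample is then assumed to vary like the other groups. Only STING ORF counts moved by over 1.5 times.

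With an estimated correlation 0 lists passed in each comparison except MDA-MB-436 STING sgRNA (1), against 6 to 13 with the preset one. With fry the numbers were 14 and 20 for Tax-R, 20, 22 and 18 for MYC siRNA, 18 and 12 for STING sgRNA, 21 for the SUM159PT STING ORF and 19 for Py230. GC correction gave 11 lists for the MDA-MB-436 STING ORF, adding nucleotide synthesis (adjusted p = 0.021), cholesterol synthesis (0.021), drug efflux (0.042) and the unfolded protein response (0.044). It added tubulins with STING sgRNA in MDA-MB-436 (0.0072), and checkpoint ligands (0.015) and class II presentation (0.048) with the SUM159PT STING ORF. Quantile normalization added class I presentation in SUM159PT Tax-R (0.037), mesenchymal markers with the SUM159PT STING ORF (0.049) and oxidative phosphorylation in Py230 (0.045). Of the overlaps, STING sgRNA between lines came to 57.1% (Fisher's exact test, p = 0.0824), and Tax-R against MYC siRNA to 62.5% in MDA-MB-436 (p = 0.306), with the 500 genes of lowest p. The latter came in SUM159PT to 54.1% after quantile normalization (Fisher's exact test, p = 4.84e-08) and 44.9% after GC correction (p = 1.48e-15).

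Of 3831 recomputed values of named genes, 3772 kept their direction and side of the threshold, 49 lost the call and 9 gained one. The other 1 changed sign, MYC with the SUM159PT STING ORF (0.006 after GC correction, adjusted p = 0.929, not called before). Single libraries decided some calls. Without SUM159PT mock replicate 1, PTGS2 (0.57, adjusted p = 0.215) and CGAS (0.24, 0.0599) lost theirs and MYC gained one (0.12, 0.0304). Without MDA-MB-436 mock replicate 1, EIF4A1 (-0.39, 0.0665) and MYC (0.08, 0.317) lost theirs, as MYC did without mock replicate 2 (0.13, 0.096) or C2 replicate 1 (0.09, 0.105). With the STING ORF, TBK1 in MDA-MB-436 lost its call without GFP replicate 1 (0.27, 0.0866) or STING ORF replicate 2 (0.28, 0.16). In SUM159PT, calls were lost without GFP replicate 1 for CGAS (0.26, 0.406), IFI16 (0.33, 0.144), HLA-B (0.35, 0.0739) and NDUFB3 (0.4, 0.127), without GFP replicate 2 for CGAS (0.32, 0.243), IFI16 (0.25, 0.266), HLA-B (0.32, 0.104) and NDUFB3 (0.47, 0.0524), and without STING ORF replicate 2 for CGAS (0.26, 0.0501) and IFI16 (0.13, 0.173). With MYC siRNA, MYC in MDA-MB-436 lost its call without control replicate 1 (-0.08, 0.124), CCL5 in SUM159PT without control replicate 2 (0.78, 0.0507) and CGAS without control replicate 1 (-0.2, 0.248), and Myc in 4T1 gained one without control replicate 1 (-0.12, 0.046) or siMYC1 replicate 2 (-0.11, 0.0376). MYC in SUM159PT Tax-R gained one without parental replicate 2 (0.21, 0.00905).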

Other observations

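The genes below were chosen after their values were seen, with no test planned.

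RB1, which restrains entry into the cell cycle, was at 78.5 ± 0.53 CPM (counts scaled to the recovered reads of the library) in SUM159PT parental libraries, 93.9 ± 2.4 in Tax-R and 54.3 ± 1.2 in Tax-R with control siRNA (n = 2 each). In the SUM159PT libraries of the CRISPR experiments it was at 3.38 ± 0.65 in mock, 5.26 ± 1.3 in C1, 3.95 ± 0.95 in C2, and 3.58 ± 0.2 and 3.68 ± 1.3 with the GFP and STING ORF (n = 2 each). In MDA-MB-436 it was at 96.9 ± 1.1 in parental, 99.2 ± 1.3 in Tax-R, 66.3 ± 1.9 in control siRNA and 53.7 ± 3.2 in mock libraries. MAOA was at 221 ± 8 CPM in SUM159PT parental, 119 ± 0.37 in Tax-R, 226 ± 13 in control siRNA and 213 ± 13 in mock libraries, and at most 3.79 ± 0.43 in any MDA-MB-436 group. MYBPC1 was at 233 ± 9.7 in SUM159PT parental, 27.6 ± 2.7 in Tax-R, 217 ± 10 in Tax-R with control siRNA and 183 ± 3.3 in mock libraries, so it differed between Tax-R groups of separate tables. MAOA and MYBPC1 thus set SUM159PT mock libraries beside the parental ones, and RB1 sets them apart. The labels do not say whether libraries of a line came from 1 stock, and a few genes do not settle it. Lines are named as in the labels, and the identity of neither MDA-MB-436 nor SUM159PT was checked against a reference, which includes whether MDA-MB-436 should carry RB1 transcripts. CPM were compared because tables were normalized separately, and differences between tables were not tested.

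Across 11912 genes, which are not independent replicates, Pearson's correlation of log2(CPM + 1) between lines was 0.962 for Tax-R and 0.91 for parental libraries, and that between parental and Tax-R was 0.898 in each line. Genes differing at least 4-fold between lines, of those at 20 CPM or more, numbered 169 in parental, 211 in mock, 352 in control siRNA and 46 in Tax-R libraries. The same count between Tax-R and parental was 164 in MDA-MB-436 and 190 in SUM159PT.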
